A study of Arabidopsis with 12 samples.

How the data were processed

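Transcripts were measured in Arabidopsis thaliana seedlings by sequencing of mRNA captured on oligo(dT) beads. Per the labels, seedlings grown for 10 days in white light were placed for 6 h in shade at a red to far-red ratio of 0.17, in liquid medium holding sorbitol or sucrose (30 mM each), and leaf portions were collected. The 12 libraries form 4 groups of 3: Col-0 with sorbitol, Col-0 with sucrose, the phytochrome A mutant phyA-211 with sorbitol, and phyA-211 with sucrose. All groups were shaded, so no comparison here measures the effect of shade itself. The labels do not say whether the replicates came from separate growth experiments, so p-values measure the spread between these samples, which may be technical.

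The authors deposited 1 table of TPM (transcript abundance scaled to the total of the library) for 32833 genes in the 12 libraries, per the file headers, with values to 2 decimals. The columns sum to between 998274.11 and 998846.46. TPM holds no read counts, so the sequencing depth of each library is unknown and no counting interval or detection floor is given. Names of fastp, cutadapt, HISAT2, DESeq2 and the TAIR10 build stand in the submitters' processing notes without versions or roles, and the program that produced the TPM values and the annotation it used are not given in the sources used here. Gene symbols came from the deposited table, and for 15 genes from a RefSeq table of assembly TAIR10.1, in which 32548 of the gene identifiers were found. That table served only for names and for the order of neighbouring genes, and no coordinates are given. Of the genes tested, 11325 have no symbol and are given by locus identifier.

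Genes with a TPM of at least 1 in at least 3 of the 12 libraries were tested, which kept 19862 genes. Values were transformed to log2(TPM + 1) and fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with a trend) as 4 group means with no replicate block, so that all 12 libraries share 1 estimate of each gene's spread (8 residual and 3.68 prior degrees of freedom). A fold change on this scale understates the change of genes with low TPM. There were 5 comparisons: sucrose against sorbitol within each genotype, phyA-211 against Col-0 under each sugar, and the genotype by sugar interaction, which is the sucrose change in phyA-211 minus that in Col-0. Every adjusted p of a gene is from limma, 2-sided, with Benjamini-Hochberg adjustment over the genes tested, and genes with adjusted p under 0.05 are said to have risen or fallen. Means carry the SD over n = 3 libraries. Single values were compared with an exact permutation test, 2-sided, whose smallest p for 3 libraries against 3 is 0.1.

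Before the data were examined, 22 gene lists were fixed: sugar-repressed genes, sugar-induced carbon and nitrogen metabolism, flavonoid synthesis, light-harvesting antenna and Rubisco small subunits, the shade-avoidance response, auxin response, cell cycle, ribosome biogenesis, cytosolic ribosomal proteins, cell wall expansion, photoreceptors and light signalling, leaf growth regulators, type-A response regulators, the circadian clock, starch breakdown, autophagy, TOR and SnRK1 components, jasmonate response, salicylate response, abscisic acid response, and markers of roots and of the shoot apical meristem as other tissues. Of their 421 entries, 401 were tested, 19 fell below the TPM filter and 1 was left out because the files give its symbol to another locus. Some genes stand in more than 1 list, so results of such lists are not independent. The shade-avoidance list shares IAA19 and IAA29 with auxin response, FHL and FHY1 with light signalling, and XTH15 with cell wall expansion. Each list was tested with limma's camera against all other genes, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 22 lists of a comparison, and again with the correlation estimated from the data. Counts of members that rose or fell are given over all genes tested and adjusted over the list alone.

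The genes named in the text were chosen by a rule also fixed beforehand. It takes PHYA in every library and, for each comparison, up to 10 rises and 10 falls of largest size among genes past the threshold with a mean of at least 5 TPM in a group and no overlap between the groups' libraries. It also takes up to 4 members of each list with the smallest adjusted p. Genes of the first kind without a symbol may be left out, and their number is given. Any other gene is said to have been chosen after its values were seen.

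The tests were tried on simulated data in which 200 of the 19862 genes had known changes, with 50 genes at each size. The changed genes were drawn only from the more abundant ones, so recovery at low TPM was not measured and may be poorer. Noise was drawn independently for each gene, so deviations shared by the genes of a library were not simulated. Far fewer genes changed than with sucrose in the data (22.1% in Col-0 and 27.5% in phyA-211). The adjustment was therefore stricter in the simulation, and its recovery does not carry over directly to the sucrose comparisons. For sucrose against sorbitol in Col-0, 70% of seeded rises of 1 log2 unit, 100% of rises of 2, 82% of falls of 1 and 98% of falls of 2 were recovered, and 6 unchanged genes were called. The same shares were 66%, 100%, 86% and 96% for sucrose in phyA-211 with 13 unchanged genes called, and 66%, 96%, 76% and 96% for genotype under sorbitol with 6. They were 66%, 98%, 80% and 98% for genotype under sucrose with 11, and 30%, 94%, 50% and 92% for the interaction with 8.

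The alternatives tried were other pseudocounts, filters and scalings, a replicate block, fits of only the groups compared, robust variance estimation, library weights, a minimum fold change, and leaving out each library in turn. The overlap of the sucrose responses was set against the number expected of independent lists. The relative size of the responses was estimated by selecting genes in one genotype without 1 replicate number, and dividing their mean signed change in the other genotype by that in the left-out pair. The sucrose comparisons of the genotypes share no library with each other, and neither do the genotype comparisons under the sugars. All of them use 1 estimate of each gene's spread, which can raise an overlap above that of independent lists.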

Results

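Messenger RNA was measured in leaf portions of 12 Arabidopsis samples, 3 in each of 4 groups. Seedlings of wild-type Col-0 and of phyA-211, a mutant of the far-red photoreceptor phytochrome A, spent 6 h in shade with either sucrose or sorbitol, a sugar alcohol given at the same concentration. Expression is given as TPM with log2 changes on the log2(TPM + 1) scale. The depth of the libraries is unknown, and each detected between 22451 and 22852 genes above 0. The most abundant transcript in all 12 libraries was CAB1, which encodes a chlorophyll-binding antenna protein, at 12755 to 30677 TPM. CAB1 is an LHCB1 copy, and reads may be split between these copies. The series title ties sucrose, the TOR kinase and phytochrome A signalling to leaf development in shade. The groups allow the sucrose response to be compared between the genotypes and the genotypes under each sugar.

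PHYA transcript followed the genotype labels in every library. In Col-0 it stood at 356, 346 and 385 TPM with sorbitol and at 343, 269.9 and 223 TPM with sucrose. In phyA-211 it stood at 32.5, 41.3 and 34.9 TPM with sorbitol and at 44.9, 44.7 and 37.4 TPM with sucrose. The mutant mean was 9.99% of the Col-0 mean under sorbitol, a log2 change of -3.29 (SE 0.155, adjusted p = 7.14e-07), and 15.2% under sucrose, a log2 change of -2.67 (SE 0.155, adjusted p = 3.8e-06). Every mutant library lay under every Col-0 library, with an exact permutation p of 0.1 under each sugar, the smallest that 3 libraries against 3 can give. PHYA itself did not pass the test for sucrose in Col-0 (log2 change -0.40, adjusted p = 0.0879) or in phyA-211 (0.22, adjusted p = 0.305).

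In shaded Col-0 leaves given sucrose, 24 of 27 starvation genes were lower, and 23 of 25 ribosome biogenesis genes and 18 of 38 cell cycle and DNA replication genes were higher, than with sorbitol. These list calls were lost with an estimated correlation. ASN1, an asparagine synthetase induced by carbon starvation, fell from 835 ± 526 TPM with sorbitol to 28.2 ± 1.07 TPM with sucrose (SD, n = 3; log2 change -4.67, SE 1.01, adjusted p = 0.00792). FIB2, a fibrillarin that modifies ribosomal RNA, rose from 44.8 ± 11.1 to 213.9 ± 15.1 TPM (log2 change 2.26, adjusted p = 0.000782). PCNA1, the clamp that holds DNA polymerase, rose from 14 ± 4.17 to 43.7 ± 5.24 TPM (log2 change 1.60, adjusted p = 0.000782). In all, 2412 of the 19862 genes tested rose and 1976 fell, a balance that depended on scaling.

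**Figure D1:**
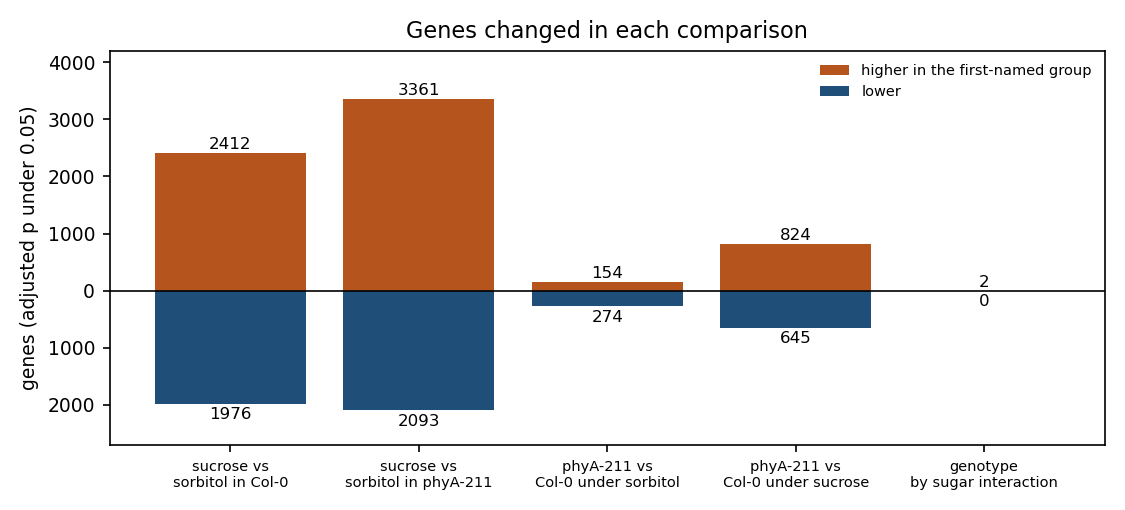
Number of genes that rose (upward bars) or fell (downward bars) at adjusted p under 0.05 in each of the 5 comparisons, from limma on log2(TPM + 1). Sucrose changed 2412 and 1976 genes in Col-0 and 3361 and 2093 in phyA-211, while the interaction held 2 rises and 0 falls.

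Of the 27 sugar-repressed genes, 24 fell and none rose in Col-0 (25 fell adjusted over the list alone), with a median log2 change of -1.99 and a camera adjusted p of 5.83e-17. That call was lost at adjusted p = 0.28 with an estimated correlation. The falls included DIN2, a beta-glucosidase of dark-treated leaves (24.0 ± 24.4 to 0.367 ± 0.0603 TPM), ERD5, a proline dehydrogenase (316 ± 71.4 to 71.8 ± 5.13 TPM), and GDH2, a glutamate dehydrogenase (802 ± 153 to 212 ± 12.2 TPM). Autophagy genes moved the same way: 13 of 21 fell (16 adjusted over the list alone), with a median of -0.70 and a camera adjusted p of 1.98e-09, against adjusted p = 0.162 with an estimated correlation. Among them were ATG5 (listed as APG5; 14.6 ± 0.562 to 7.61 ± 0.809 TPM), which acts in conjugating ATG8 to membranes, and ATG8C (70.07 ± 6.89 to 34.7 ± 7.29 TPM).

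Of the 25 ribosome biogenesis genes tested, 23 rose (23 adjusted over the list alone), with a median of 1.18 and a camera adjusted p of 2.51e-13, against adjusted p = 0.386 with an estimated correlation. NOP56, a core protein of small nucleolar ribonucleoproteins, rose from 65.3 ± 18.1 to 212 ± 30.0 TPM. NAP57, the pseudouridine synthase of these particles, rose from 54.9 ± 11.8 to 154 ± 10.7 TPM. Cytosolic ribosomal proteins rose in 21 of 23 cases (22 adjusted over the list alone), with a median of 0.75 and a camera adjusted p of 4.03e-12, against adjusted p = 0.362 with an estimated correlation. RPS6, whose protein is phosphorylated downstream of TOR, rose from 361 ± 49.9 to 818 ± 9.88 TPM, and RPS5B from 154 ± 15.6 to 308 ± 17.5 TPM. A caution is that reads of these near-identical gene pairs may be split between copies. Cell cycle and DNA replication genes rose in 18 of 38 cases and fell in none (19 and 0 adjusted over the list alone), with a median of 0.34 and a camera adjusted p of 1.13e-05, against adjusted p = 0.471 with an estimated correlation. TSO2, a subunit of the enzyme that makes deoxyribonucleotides, rose from 30.8 ± 4.70 to 81.02 ± 8.92 TPM.

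Flavonoid synthesis genes rose in 11 of 17 cases (11 adjusted over the list alone; median 0.78; camera adjusted p = 3.07e-06, and adjusted p = 0.103 with an estimated correlation). TT4, which encodes chalcone synthase, the entry enzyme of the pathway, rose from 128 ± 49.9 to 339 ± 46.3 TPM, and FLS1, flavonol synthase, from 20.4 ± 4.70 to 58.1 ± 8.51 TPM. Of 16 sugar-induced genes, 8 rose and none fell (9 and 2 adjusted over the list alone; median 0.68; camera adjusted p = 0.0187, and adjusted p = 0.643 with an estimated correlation). Among them G6PD3, a glucose-6-phosphate dehydrogenase, rose from 6.06 ± 0.984 to 28.04 ± 4.18 TPM. Type-A response regulators, early targets of cytokinin, rose in 4 of 8 cases (4 adjusted over the list alone; median 0.56; camera adjusted p = 0.0189, and adjusted p = 0.386 with an estimated correlation). ARR7 went from 2.13 ± 0.396 to 9.53 ± 1.08 TPM.

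Shade-avoidance genes leaned down in Col-0 with sucrose: 9 of 27 fell and 2 rose (9 and 2 adjusted over the list alone), with a median of -0.29 and a camera adjusted p of 0.000924, against adjusted p = 0.162 with an estimated correlation. PKS4, a phytochrome substrate, fell from 23.8 ± 1.22 to 11.3 ± 0.867 TPM, PIL2, a PIF-like transcription factor, from 48.6 ± 4.39 to 23.4 ± 5.68 TPM. PAR1, a repressor of shade responses, fell from 85.7 ± 19.0 to 35.5 ± 6.81 TPM, while IAA19 rose from 29.96 ± 0.921 to 50.8 ± 7.82 TPM. The circadian clock list had 2 falls among 15 genes (1 adjusted over the list alone; median -0.25; camera adjusted p = 0.0122, and adjusted p = 0.396 with an estimated correlation). These were BOA, a clock transcription factor (14 ± 2.64 to 5.78 ± 0.620 TPM), and PRR7 (100.3 ± 12.7 to 65.3 ± 14.1 TPM, adjusted p = 0.0475). The abscisic acid list had 3 falls among 11 (4 adjusted over the list alone; median -0.29; camera adjusted p = 0.0122, and adjusted p = 0.386 with an estimated correlation). These were COR47, LTI30 and KIN2, dehydrins and cold-response genes, where reads of KIN1 and KIN2 may be split between copies.

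Camera called none of the other lists in Col-0. Auxin response genes rose in 2 and fell in 5 of 27 cases (2 and 5 adjusted over the list alone). Cell wall expansion genes rose in 7 and fell in 3 of 22 (11 and 4 adjusted over the list alone). Photoreceptor and light signalling genes rose in 2 and fell in 5 of 26 (2 and 5 adjusted over the list alone), and leaf growth regulators in 3 and 3 of 26 (3 and 3 adjusted over the list alone). Antenna and Rubisco genes rose in 1 (RBCS1B) and fell in 1 (LHB1B1, an LHCB1 copy) of 24 (1 and 0 adjusted over the list alone, with reads possibly split between copies). XTH24, a cell wall enzyme, fell from 822 ± 355 to 185 ± 20.6 TPM. Among leaf growth regulators, ARGOS and ARL, which promote organ growth, fell by 1.39 and 1.35 on the log2 scale. Starch breakdown had 1 rise (LSF1) and 1 fall (BAM1) in 12, TOR and SnRK1 components 2 falls in 8 (LST8-1 and KIN11), and the salicylate list 1 fall in 7 (WRKY70), with the same counts adjusted over the list alone. No member of the jasmonate, root or meristem lists (9, 8 and 4 genes) passed. By size alone, the named rises included IPMI1, IPMI2 and IMD1, enzymes of the chain elongation that precedes glucosinolates and leucine, and GPT2, a plastid glucose-6-phosphate carrier. IPMI2, IMD1 and GPT2 had log2 changes of 2.74, 2.68 and 3.15. IPMI1 went from 0.123 ± 0.214 to 12.2 ± 2.18 TPM, and no fold is given because it was listed at 0 in 2 of the 3 Col-0 sorbitol libraries. The named falls included GLYI7 (-4.50), BCAT-2, a branched-chain aminotransferase (-4.17), GAT1_2.1 (-3.85), and THA1, a threonine aldolase (-3.84). The U1 small nuclear RNA genes U1.6 and U1.7 were both listed at 0 in the 3 Col-0 sorbitol libraries and at 29.8, 23.0 and 12.9 TPM with sucrose, and such short genes were also listed at 0 in libraries of other groups, so no fold is given. Reads of U1.6 and U1.7 may be split between copies. The 8 genes chosen by size that have no symbol are left out.

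Rescaling by the median ratio gave 2454 rises and 2894 falls in Col-0, 45.9% rises against 55%, and quantile normalization gave 51.7%. Weighting the libraries by their estimated quality gave 4777 rises and 4152 falls in Col-0, and a doubling or halving was reached by 579 and 540 genes. Rises numbered 1144 without Col-0 sorbitol replicate 3, 1388 without Col-0 sucrose replicate 1 and 1350 without Col-0 sucrose replicate 2, and falls numbered 1225 without Col-0 sorbitol replicate 3 and 1124 without Col-0 sucrose replicate 2.

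In phyA-211 with sucrose, 25 of 27 starvation and 14 of 21 autophagy genes were lower, and 24 of 25 ribosome biogenesis, 23 of 38 cell cycle and 8 of 17 flavonoid genes were higher. These list calls too were lost with an estimated correlation. ASN1 fell from 944 ± 88.3 to 105 ± 93.8 TPM (SD, n = 3; log2 change -4.26, SE 1.01, adjusted p = 0.0117). FIB2 rose from 45.4 ± 1.26 to 193 ± 90.5 TPM (log2 change 1.97, adjusted p = 0.00168). TT4 rose from 26.0 ± 3.41 to 107 ± 1.69 TPM (log2 change 2.02, adjusted p = 0.00121). In all, 3361 genes rose and 2093 fell, a balance that depended on scaling.

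**Figure D2:**
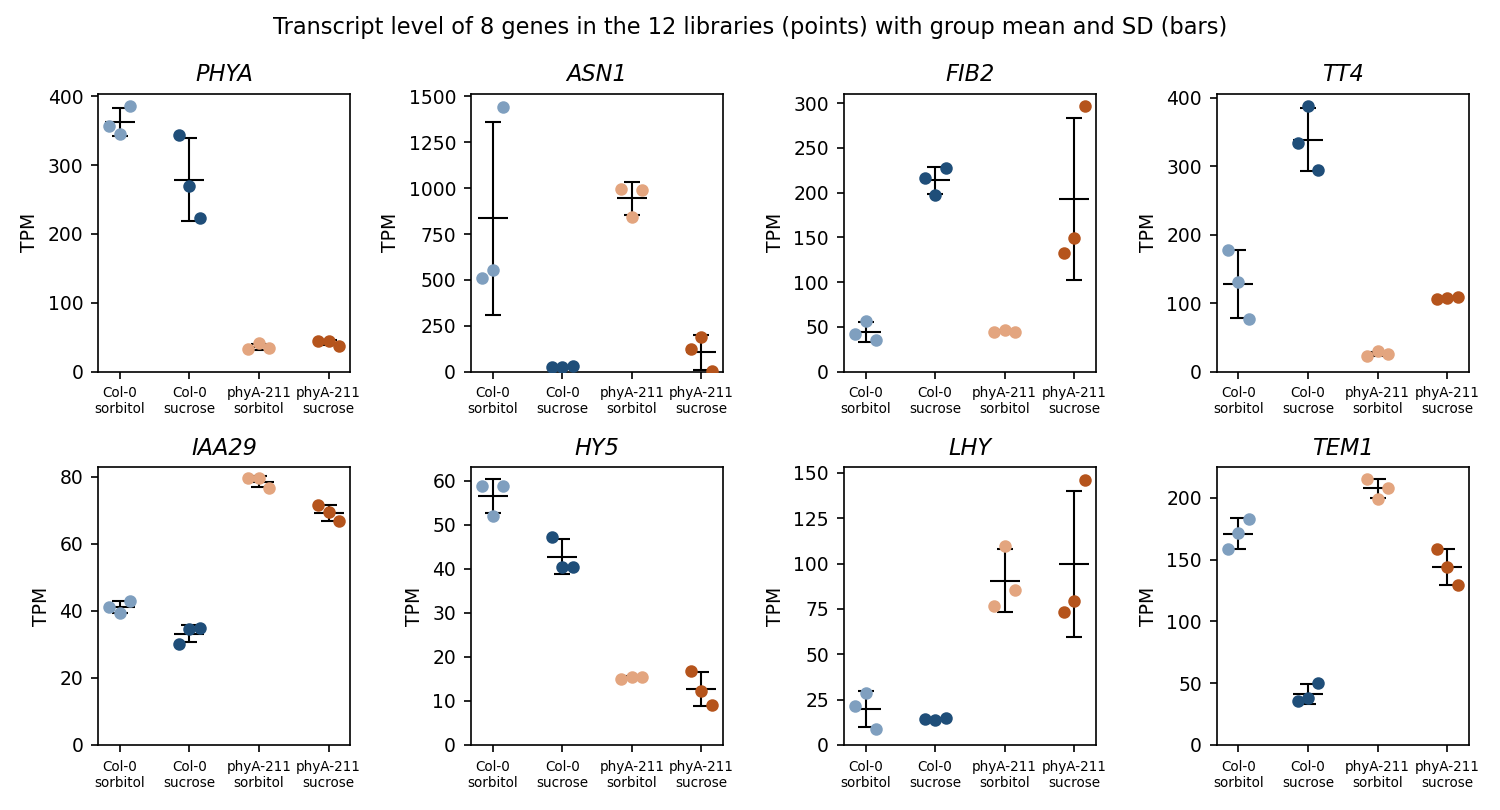
TPM of 8 genes in each library (points) with the group mean and SD, by genotype and sugar. ASN1 lies lower and FIB2 higher with sucrose in both genotypes, PHYA and HY5 lie lower in phyA-211, and IAA29 and LHY lie higher there.

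The sugar-repressed list had 25 falls among 27 (25 adjusted over the list alone; median -1.86; camera adjusted p = 1.45e-16, and adjusted p = 0.28 with an estimated correlation). ATL8 fell from 32.0 ± 5.37 to 6.38 ± 1.25 TPM and BGAL4, a beta-galactosidase, from 208 ± 22.4 to 34.4 ± 22.3 TPM. Autophagy genes fell in 14 of 21 cases (15 adjusted over the list alone; median -0.61; camera adjusted p = 9.13e-08, and adjusted p = 0.25 with an estimated correlation). ATG8E went from 259 ± 88.8 to 66.5 ± 36.2 TPM. Ribosome biogenesis genes rose in 24 of 25 cases (25 adjusted over the list alone; median 1.17; camera adjusted p = 1e-11, and adjusted p = 0.426 with an estimated correlation). Ribosomal proteins rose in 18 of 23 cases (18 adjusted over the list alone; median 0.65; camera adjusted p = 6.56e-08, and adjusted p = 0.426 with an estimated correlation), with RPS6 at 372 ± 15.5 to 850.1 ± 188 TPM. Cell cycle genes rose in 23 of 38 cases (23 adjusted over the list alone; median 0.57; camera adjusted p = 6.56e-08, and adjusted p = 0.426 with an estimated correlation). PRL, the replicative helicase subunit MCM7, rose from 12.6 ± 2.29 to 32.5 ± 6.36 TPM and MCM4 from 9.89 ± 1.78 to 23.4 ± 4.01 TPM.

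Flavonoid genes rose in 8 of 17 cases in phyA-211 (9 adjusted over the list alone; median 0.50; camera adjusted p = 0.000138, and adjusted p = 0.25 with an estimated correlation), with FLS1 at 3.58 ± 0.565 to 18.5 ± 3.22 TPM. Sugar-induced genes rose in 8 and fell in 2 of 16 cases (9 and 2 adjusted over the list alone; median 0.81; camera adjusted p = 0.0223, and adjusted p = 0.652 with an estimated correlation). APL3, a subunit of ADP-glucose pyrophosphorylase in starch synthesis, went from 3.90 ± 0.0896 to 15.5 ± 6.64 TPM. The abscisic acid list had 4 falls among 11 (5 adjusted over the list alone; median -1.0; camera adjusted p = 3.78e-05, and adjusted p = 0.25 with an estimated correlation). These were LTI30 (50.5 ± 16.1 to 4.44 ± 1.64 TPM), KIN1, KIN2 and COR47, with reads of KIN1 and KIN2 possibly split. Clock genes fell in 5 of 15 cases (6 adjusted over the list alone; median -0.42; camera adjusted p = 0.000217, and adjusted p = 0.28 with an estimated correlation). ELF4, an evening clock gene, fell from 22.03 ± 2.65 to 10.0 ± 0.790 TPM. The auxin list had 3 rises and 5 falls among 27 (3 and 5 adjusted over the list alone; median -0.18; camera adjusted p = 0.0301, and adjusted p = 0.652 with an estimated correlation). GH3.3, an enzyme that conjugates auxin, rose from 37.98 ± 14.3 to 78.4 ± 13.2 TPM and IAA14 fell from 23.8 ± 5.37 to 13.97 ± 2.15 TPM.

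Camera did not call the shade-avoidance list for sucrose in phyA-211 (median 0.11, adjusted p = 0.706). It had 4 rises and 5 falls among 27 (4 and 5 adjusted over the list alone). PIL1 rose from 26.02 ± 5.54 to 63.2 ± 24.7 TPM and FHL, a partner of phytochrome A in nuclear import, fell from 17.3 ± 2.1 to 9.46 ± 1.79 TPM. Cell wall genes rose in 8 and fell in 2 of 22 cases, leaf growth regulators rose in 4 of 26 (TCP24, ANT, TCP4 and TCP2), and photoreceptor and light signalling genes fell in 4 of 26 (HYH, FHL, FHY1 and PIL6, the PIF5 gene). Starch breakdown genes rose in 3 (SEX4, LSF1, PHS1) and fell in 1 (BAM1) of 12, and type-A response regulators rose in 2 of 8 (ARR4 and ARR7). Each of these counts was the same adjusted over the list alone. JAZ7 and TIFY7, which encode jasmonate repressors, fell (2 of 9, and 2 adjusted over the list alone). WRKY70 of the salicylate list rose and LST8-1 of the TOR list fell (both 0 adjusted over the list alone), and no antenna, Rubisco or meristem gene passed. Among the 8 root markers, TIP2;3, a root aquaporin, fell by 1.98 on the log2 scale (18.9 ± 14.5 to 3.39 ± 1.79 TPM, adjusted p = 0.0411), and the list was not called (0 adjusted over the list alone; median -0.40; camera adjusted p = 0.127).

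Named changes of large size in phyA-211 included rises of GPT2 (log2 change 3.90) and FTM1, a stearoyl carrier protein desaturase (3.6), and falls of GAT1_2.1 (-4.44), GLYI7 (-4.25), DIN2 (-3.82), THA1 (-3.71) and BCAT-2 (-3.42). The microRNA gene ath-MIR5021 also fell, from 29.3 ± 4.56 to 1.99 ± 3.45 TPM, and no fold is given because it was listed at 0 in 2 of the 3 phyA-211 sucrose libraries. The microRNA gene ath-MIR833a was listed at 0 in the 9 libraries of the other groups and at 15.2, 15.9 and 23.6 TPM in phyA-211 with sucrose. It rose in the test, and no fold is given because the plastid gene rpl32, chosen after its values were seen, was also listed at 0 in 6 libraries. Left out are 10 genes without a symbol. Replicate 3 of phyA-211 with sucrose stood apart from its group, with ASN1 at 4.07 TPM against 123 and 189 TPM and FIB2 at 297 TPM against 132 and 149.6 TPM, which widens the SD of this group's sugar-responsive genes.

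Rescaling by the median ratio moved the median change of all genes by -0.13 for this comparison and gave 2795 rises and 2980 falls, 48.4% rises against 61.6%. Quantile normalization gave 56.9% and library weights gave 7345 rises and 4057 falls. Fitting only the groups compared gave 1621 and 1088. Leaving out phyA-211 sorbitol replicate 1, sorbitol replicate 3 or sucrose replicate 3 gave 1786, 1345 or 1904 rises, with 982 falls without phyA-211 sorbitol replicate 3.

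The responses of the genotypes overlapped widely. Of the genes that rose in Col-0, 1908 also rose in phyA-211, against 408 expected of independent lists, and 1328 fell in both against 208 expected. The lists are not fully independent, since both rest on 1 estimate of each gene's spread. The log2 changes correlated at r = 0.768 across genes, which are not independent replicates. Only 4 genes passed in opposite directions, and they were chosen for naming after their values were seen. WRKY70, a defence transcription factor, fell in Col-0 (-0.98) and rose in phyA-211 (0.64), IQD22 and AT5G12050 did likewise, and AT5G05635 rose in Col-0 and fell in phyA-211. The mean signed change of Col-0 sucrose genes in phyA-211 was 1.03, 0.958 and 0.795 times that in left-out Col-0 pairs (mean 0.928 ± 0.12). With the genotypes exchanged the ratios were 1.09, 1.35 and 0.673 (mean 1.04 ± 0.342). Without phyA-211 sucrose replicate 3 the first set was 0.832, 0.809 and 0.671, and 2 ratios of the exchanged set could be had, 0.970 and 1.18.

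Under sorbitol, several flavonoid, light-signalling and clock genes were lower and several shade-avoidance genes higher in shaded leaves of phyA-211 than of Col-0. HY5, a transcription factor that promotes light responses, fell from 56.5 ± 3.95 TPM in Col-0 to 15.3 ± 0.284 TPM in phyA-211 (SD, n = 3; log2 change -1.82, adjusted p = 0.000267). FLS1 fell from 20.4 ± 4.70 to 3.58 ± 0.565 TPM (log2 change -2.21, adjusted p = 8.57e-05). IAA29, a shade-induced auxin gene, rose from 41.1 ± 1.76 to 78.6 ± 1.76 TPM (log2 change 0.92, adjusted p = 0.000434). In all, 154 genes rose and 274 fell.

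**Figure D3:**
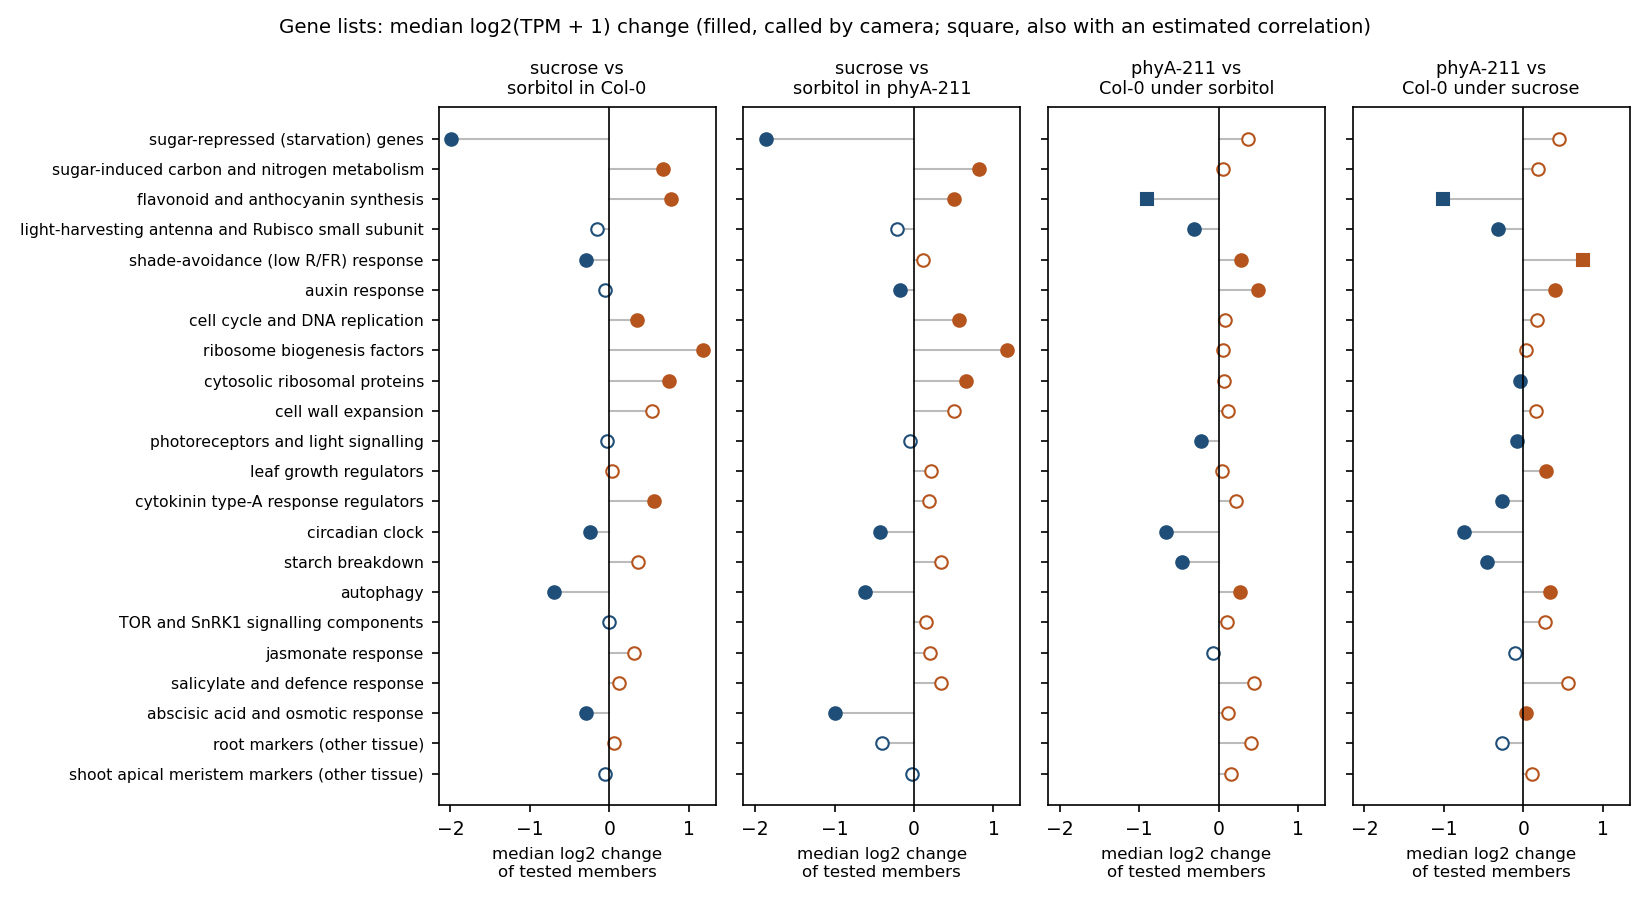
Median log2 change of each of the 22 lists for sucrose in each genotype and for genotype under each sugar, coloured by its sign, filled where camera called the list with the preset correlation and square where also with an estimated correlation. The squares are flavonoid synthesis in both genotype comparisons and shade avoidance for genotype under sucrose. The abscisic acid list for genotype under sucrose has a median of 0.03 and a downward camera call.

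Of 17 flavonoid genes, 7 were lower in phyA-211 under sorbitol and none was higher (10 adjusted over the list alone). The median was -0.90 and the camera call held both with the preset correlation (adjusted p = 7.13e-18) and with an estimated one (adjusted p = 0.00245). TT4 stood at 26.0 ± 3.41 TPM against 128 ± 49.9 TPM, and F3H, the next hydroxylase of the pathway, at 4.35 ± 0.712 against 20 ± 1.49 TPM. Photoreceptor and light signalling genes fell in 7 and rose in 1 of 26 cases (9 and 1 adjusted over the list alone; median -0.23; camera adjusted p = 3.38e-09, and adjusted p = 0.173 with an estimated correlation). The falls include PHYA, the mutated gene itself, which adds to the call, and the list was not tested without it. Besides PHYA and HY5 the falls included ELIP1, a light-induced plastid protein, at 0.627 ± 0.103 against 26.9 ± 13.0 TPM. The rise was FHL, at 17.3 ± 2.1 against 6.29 ± 0.939 TPM. Clock genes fell in 7 and rose in 2 of 15 cases (9 and 3 adjusted over the list alone; median -0.66; camera adjusted p = 3.67e-08, and adjusted p = 0.103 with an estimated correlation). ELF4 stood at 22.03 ± 2.65 against 95.2 ± 18.8 TPM, and GI, an evening-phased clock gene, at 12.5 ± 4.51 against 40.5 ± 2.11 TPM. The rises were the morning genes LHY (log2 change 2.26) and RVE8 (1.22), named after their values were seen.

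Shade-avoidance genes rose in 8 and fell in 1 of 27 cases in phyA-211 under sorbitol (10 and 3 adjusted over the list alone; median 0.28; camera adjusted p = 0.000202, and adjusted p = 0.103 with an estimated correlation). PKS4 stood at 43.2 ± 2.27 against 23.8 ± 1.22 TPM and CKX5, a cytokinin oxidase, at 17.4 ± 5.21 against 6.73 ± 1.23 TPM. Auxin genes rose in 4 and fell in 1 of 27 cases (13 and 1 adjusted over the list alone; median 0.50; camera adjusted p = 9.02e-07, and adjusted p = 0.173 with an estimated correlation). Antenna and Rubisco genes fell in 2 of 24 cases (2 adjusted over the list alone; median -0.31; camera adjusted p = 4.85e-07, and adjusted p = 0.565 with an estimated correlation). These were RBCS1B, a Rubisco small subunit whose reads may be split with its copies, at 797 ± 118 against 2441 ± 389 TPM, and Lhca6. Starch breakdown genes fell in 2 of 12 cases (8 adjusted over the list alone; median -0.46; camera adjusted p = 2.04e-09, and adjusted p = 0.173 with an estimated correlation). They were CT-BMY, the plastid beta-amylase BAM3, at 79.97 ± 28.5 against 240.6 ± 99.3 TPM, and PHS2, a cytosolic phosphorylase. The autophagy list was called upward with no member passing (median 0.26, camera adjusted p = 0.0105, and adjusted p = 0.565 with an estimated correlation).

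The only other list member to pass under sorbitol was XTH17 of the cell wall list, which rose from 26.9 ± 7.72 to 66.5 ± 11 TPM (2 rises and 1 fall adjusted over the list alone). None of the sugar-repressed, sugar-induced, ribosome biogenesis, ribosomal protein, cell cycle, leaf growth, type-A regulator, TOR and SnRK1, jasmonate, salicylate, abscisic acid, root and meristem genes passed over all genes. Adjusted over the list alone, 2 type-A regulators and 1 salicylate gene were higher. By size, QRT1, a pectin methylesterase of pollen separation, rose from 0.107 ± 0.0379 to 66.1 ± 6.61 TPM (log2 change 5.92, adjusted p = 6.46e-10). MRD1 rose by a log2 change of 3.77 and QQS, a gene that affects starch content, by 3.09. ELIP1 (-3.96), FBA5, an aldolase (-2.86), MSRB6, a methionine sulfoxide reductase (-2.73), and CYP706A6 (-2.37) fell. U1.6 was listed at 52.8, 27.6 and 19.1 TPM in phyA-211 with sorbitol and at 0 in Col-0 with sorbitol. U1.7, also a U1 gene, was listed at 0, 27.6 and 19.1 TPM in phyA-211 with sorbitol, and reads may be split between these genes. Left out are 11 genes without a symbol.

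Falls under sorbitol numbered 427 after median-ratio rescaling and 414 after quantile normalization. Rises and falls were 93 and 178 with only the groups compared and 2729 and 2294 with library weights, and 76 and 136 genes at least doubled or halved. Leaving out Col-0 sorbitol replicate 1 gave 54 rises and 103 falls, Col-0 sorbitol replicate 2 gave 72 and 149. Leaving out phyA-211 sorbitol replicate 1 gave 159 falls, sorbitol replicate 2 gave 100 rises, sorbitol replicate 3 gave 49 and 103, and phyA-211 sucrose replicate 3 gave 319 and 465.

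Under sucrose, the genotypes differed in more genes, 824 higher and 645 lower in phyA-211, a balance that turned round under other scalings. The shade-avoidance list rose as a group. HB-2, the shade-induced homeobox gene ATHB2, rose from 69.95 ± 1.37 TPM in Col-0 to 165 ± 27.1 TPM in phyA-211 (SD, n = 3; log2 change 1.21, adjusted p = 0.000444). PKS4 rose from 11.3 ± 0.867 to 32.2 ± 4.53 TPM (log2 change 1.43, adjusted p = 5.42e-05). ELF4 fell from 81.8 ± 14.4 to 10.0 ± 0.790 TPM (log2 change -2.90, adjusted p = 3.01e-06). HY5 fell from 42.7 ± 3.99 to 12.7 ± 3.91 TPM (log2 change -1.71, adjusted p = 0.000158).

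Of 27 shade-avoidance genes, 15 rose and 1 fell in phyA-211 under sucrose (19 and 1 adjusted over the list alone). The median was 0.75, and the camera call held with the preset correlation (adjusted p = 5.07e-09) and with an estimated one (adjusted p = 0.0135). The flavonoid list had 8 falls among 17 (12 adjusted over the list alone; median -1.01) and its call also held with the preset correlation (adjusted p = 5.16e-15) and an estimated one (adjusted p = 0.00452). UGT78D2, a flavonoid glucosyltransferase, stood at 23.5 ± 2.70 against 62.5 ± 2.94 TPM. Clock genes fell in 8 and rose in 3 of 15 cases (10 and 3 adjusted over the list alone; median -0.74; camera adjusted p = 5.6e-08, and adjusted p = 0.0998 with an estimated correlation). GI stood at 12.8 ± 0.943 against 54.3 ± 14.9 TPM, and the rises were LHY, CCA1 and RVE8, these 3 named after their values were seen. Photoreceptor and light signalling genes fell in 8 and rose in 2 of 26 cases (9 and 3 adjusted over the list alone; median -0.08; camera adjusted p = 2.52e-05, and adjusted p = 0.381 with an estimated correlation). Here too PHYA, the mutated gene, is among the falls, and the list was not tested without it. ELIP2 stood at 4.1 ± 0.741 against 65.3 ± 13.3 TPM.

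Antenna and Rubisco genes fell in 3 of 24 cases under sucrose (3 adjusted over the list alone; median -0.31; camera adjusted p = 1.25e-06, and adjusted p = 0.457 with an estimated correlation). RBCS1B, with reads possibly split between copies, stood at 949.8 ± 147 against 4559 ± 325 TPM. Starch breakdown genes fell in 4 of 12 cases (8 adjusted over the list alone; median -0.46; camera adjusted p = 2.66e-07, and adjusted p = 0.381 with an estimated correlation), with CT-BMY at 61.4 ± 10.7 against 269 ± 27.0 TPM. Auxin genes rose in 7 and fell in 2 of 27 cases (13 and 3 adjusted over the list alone; median 0.40; camera adjusted p = 0.0355, and adjusted p = 0.531 with an estimated correlation), with GH3.3 at 78.4 ± 13.2 against 23.6 ± 1.01 TPM. Leaf growth regulators rose in 4 of 26 cases (4 adjusted over the list alone; median 0.28; camera adjusted p = 0.0498, and adjusted p = 0.457 with an estimated correlation). They were ARL (log2 change 1.79), ARGOS, GRF7 and AT4G14720. The abscisic acid list was called downward (camera adjusted p = 0.0087, and adjusted p = 0.381 with an estimated correlation), with a mean change of -0.49 and a median of 0.03. KIN1, LTI30 and KIN2 fell among its 11 members (3 adjusted over the list alone), with reads of KIN1 and KIN2 possibly split.

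Also called under sucrose were autophagy upward (1 rise, ATG13, in 21, and 0 adjusted over the list alone; median 0.34; camera adjusted p = 0.00552, and adjusted p = 0.423 with an estimated correlation) and type-A regulators downward (no member passing; median -0.27; camera adjusted p = 0.0355, and adjusted p = 0.392 with an estimated correlation). Ribosomal proteins were called downward (no member passing; median -0.04; camera adjusted p = 0.0355, and adjusted p = 0.773 with an estimated correlation), a median that turned to 0.08 under quantile normalization. XTH15 and XTH24 of the cell wall list (3 adjusted over the list alone), WRKY70 of the salicylate list (3 higher and 1 lower adjusted over the list alone) and TPS10 of the sugar-repressed list (0 adjusted over the list alone) rose. RNR2A of the cell cycle list (0 adjusted over the list alone) and TIFY7 of the jasmonate list (1 adjusted over the list alone) fell. No member of the sugar-induced, ribosome biogenesis, TOR and SnRK1, root or meristem lists passed. Large named changes were QRT1 (log2 change 5.31), MRD1 (4.03) and ath-MIR833a upward, the last listed at 0 in all Col-0 libraries. Downward were ELIP1 (-4.54), FBA5 (-3.91), ELIP2 (-3.69), CP12-2, a regulator of the Calvin cycle (-3.54), CYP706A6 (-2.94) and CGA1, a GATA factor of chloroplast development (-2.93). U2.3 was listed at 17.4, 53.2 and 6.39 TPM in Col-0 with sucrose and at 0 in phyA-211 with sucrose. Left out are 10 genes without a symbol.

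The genotype differences under the sugars shared 106 rises against 6.39 expected of independent lists and 246 falls against 8.90 expected, with 0 genes in opposite directions by limma. These lists too rest on 1 estimate of each gene's spread. Among the 100 tested loci nearest to PHYA, 6.00% were called in a genotype comparison against 7.81% of the others (Fisher's exact test, 2-sided, p = 0.707). Median-ratio rescaling moved the median of all genes under sucrose by -0.11 and gave 602 rises and 912 falls, 39.8% rises against 56.1%. Quantile normalization gave 43.3%, only the groups compared gave 266 and 388, library weights gave 6158 and 2470, and 179 and 292 genes at least doubled or halved. Leaving out phyA-211 sorbitol replicate 3 gave 544 rises, Col-0 sucrose replicate 2 gave 254 rises and 315 falls, Col-0 sucrose replicate 3 gave 377 rises. Leaving out phyA-211 sucrose replicate 2 gave 319 rises, 408 falls and 7 called lists instead of 12.

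The interaction asked directly whether sucrose changed genes differently in the genotypes. TEM1, a repressor of flowering and gibberellin synthesis, fell with sucrose from 171 ± 12.4 to 41.4 ± 7.87 TPM in Col-0 and from 208 ± 7.97 to 144 ± 14.5 TPM in phyA-211, an interaction of 1.51 log2 units (SE 0.190, adjusted p = 0.0473). The other gene to pass was ath-MIR833a (limma adjusted p = 5.33e-05, with 0.0438 at a pseudocount of 0.1 and 0.041 at a minimum of 5 TPM). Its zeros in the 9 libraries of the other groups lower the estimated spread, so these p-values are likely too small. No gene passed as lower by limma, and 792 genes had an unadjusted p under 0.05 in either direction. Across settings the TEM1 interaction stayed between 1.42 and 1.66 log2 units, and it passed with a pseudocount of 0.1, with a minimum of 5 TPM and with library weights (adjusted p = 0.000119). It did not pass with no filter (adjusted p = 0.0785), median-ratio rescaling (adjusted p = 0.264), quantile normalization (adjusted p = 0.151), the replicate block (adjusted p = 0.236) or robust eBayes (adjusted p = 0.0503). With 1 library left out it passed only without Col-0 sucrose replicate 3. Listed above 0 only in the 3 phyA-211 sucrose libraries, ath-MIR833a fails the TPM filter and is not tested when any of them is left out. Library weights gave 980 higher and 396 lower. The weights were estimated from these same libraries, so counts and p-values with them may be too favourable.

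**Figure D4:**
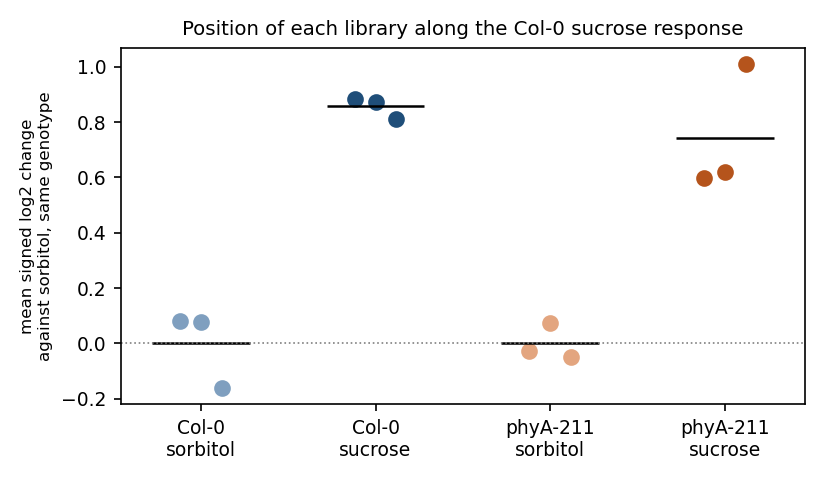
Position of each library along the sucrose response, the mean log2 difference from its genotype's sorbitol mean over the 4388 genes changed by sucrose in Col-0, signed by their direction there. The phyA-211 sucrose libraries lie at 0.599, 0.621 and 1.01 and the Col-0 sucrose libraries between 0.811 and 0.884. The genes were chosen in these Col-0 libraries, which raises the Col-0 positions, so the genotypes' heights are not to be compared.

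No list had a member past the interaction test over all genes, and camera called 7 lists, none with an estimated correlation. Adjusted over the list alone, 3 shade-avoidance genes and 1 leaf growth regulator were higher and 4 type-A regulators and 2 abscisic acid genes were lower. By the same count 1 cell wall and 1 salicylate gene were higher and 1 photoreceptor and 1 clock gene were lower. Shade-avoidance genes had a median of 0.27 (camera adjusted p = 8.67e-06, and adjusted p = 0.0906 with an estimated correlation), with PIL2 at 1.15 (adjusted p = 0.321) and XTH15 at 1.55 (adjusted p = 0.695). Leaf growth regulators had a median of 0.20 (camera adjusted p = 0.0138, and adjusted p = 0.595 with an estimated correlation), with ARL at 1.3 (adjusted p = 0.697). Type-A regulators had a median of -0.59 (camera adjusted p = 4.77e-05, and adjusted p = 0.215 with an estimated correlation), with ARR7 at -1.16 (adjusted p = 0.69). Abscisic acid genes had a median of -0.30 (camera adjusted p = 0.000569, and adjusted p = 0.368 with an estimated correlation) and ribosomal proteins one of -0.16 (camera adjusted p = 0.00563, and adjusted p = 0.902 with an estimated correlation). Jasmonate genes had a median of -0.15 (camera adjusted p = 0.0369, and adjusted p = 0.405 with an estimated correlation) and root markers one of -0.53 (camera adjusted p = 0.0306, and adjusted p = 0.902 with an estimated correlation). Without phyA-211 sorbitol replicate 2 the interaction called 4 lists.

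The 10 most abundant genes took 7.18 ± 0.497% of the TPM of Col-0 with sucrose and 9.36 ± 0.869% with sorbitol (SD, n = 3), and every sucrose library lay under every sorbitol library. The exact permutation p of 0.1 is the smallest that 3 libraries against 3 can give, so this test could not pass. In phyA-211 they took 7.06 ± 1.81% against 8.73 ± 0.962% (exact permutation p = 0.2), with libraries of the sugars overlapping.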

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

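The chromosome test of the genes near 0 in Col-0, the test of the library's label and the clock test were chosen after the results were seen.

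The interaction passed for TEM1, at 1.51 log2 units, and for ath-MIR833a, with a limma adjusted p of 5.33e-05. The latter gene was listed at 0 in the 9 libraries of the other groups. Without read counts such zeros cannot be told from missed detection, so its differing response stays uncertain. Those zeros also lower the estimated spread, so its adjusted p is likely too small. For TEM1 the interaction stayed between 1.42 and 1.66 log2 units in every setting, and it passed with a pseudocount of 0.1, with a minimum of 5 TPM and with library weights (adjusted p = 0.000119). The weights were estimated from these same libraries, so that p may be too small. The TEM1 interaction lost its call with no filter, both rescalings, the replicate block and robust eBayes. It also lost the call in every fit leaving out 1 library except the fit without Col-0 sucrose replicate 3. Splits of the libraries do not tell whether the count of 2 genes is beyond chance. In 13 of 100 splits, the real one included, at least as many genes passed, with 4 in the highest other. The splits exchange genotype labels within each sugar separately, so an uneven exchange turns genotype differences into an apparent interaction and widens the spread. Camera's preset correlation also picked out 7 lists by their interaction medians: shade avoidance (0.274), leaf growth regulators (0.195), cytosolic ribosomal proteins (-0.164), type-A response regulators (-0.594), jasmonate (-0.148), abscisic acid (-0.298) and root markers (-0.535). Chance is not excluded for these lists either. Of the 100 splits, 65 called 7 or more lists, the real one included, with 13 in the highest other, and the same limit holds.

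With 3 libraries against 3, the 10 splits cannot give a share under 0.05. The real split was the highest for genes changed, alone among the 10 (1 of 10), with 4388 genes against 1 in the highest other for sucrose in Col-0 and 5454 against 1 for sucrose in phyA-211. For genotype the counts were 428 against 55 under sorbitol and 1469 against 2 under sucrose. The number of lists called with the preset correlation was matched or passed by another split in 3 of these 4 comparisons: 10 against 10 (4 of 10 splits as high) for sucrose in phyA-211, and 8 against 13 (5 of 10) and 12 against 12 (2 of 10) for genotype under sorbitol and sucrose. For sucrose in Col-0 it was 11 against 10 (1 of 10). The other splits keep part of the real difference, so these shares do not tell whether the list counts are beyond chance.

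The transcripts of 3 genes stood near 0 in Col-0 and at 5 TPM or more in phyA-211 under both sugars: QRT1 (0.107 against 66.1 TPM under sorbitol), AT5G24240, a phosphatidylinositol kinase-like gene (0.253 against 21.6 TPM), and AT2G06305, a noncoding RNA (0 against 10.4 TPM). Variants beside these 3 genes, carried along with the PHYA locus on chromosome 1, are argued against. Of the 3 genes, 0 lie on that chromosome. A variant linked to PHYA that acts on genes elsewhere was not tested by position and stays open. A first test, of the share among the 100 loci nearest to PHYA, found 0 but left an exact upper bound of 70.8% and decided nothing. Differences between the lines that are unlinked to PHYA may account for them, and a permutation test for neighbouring positions (p = 1) did not decide it. Loss of phytochrome A stays open as the biological explanation, since only 1 mutant line was analysed here. Linked variants beside the gene itself stay open for AT1G09557, a noncoding RNA among the 100 loci nearest to PHYA that fell outside this pattern. In phyA-211 it stood at 31.2 against 3.06 TPM in Col-0 under sorbitol (limma adjusted p = 0.0187). Under sucrose it stood at 38.4 against 0.443 TPM (limma adjusted p = 0.00125).

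Replicate 3 of phyA-211 with sucrose lay farther along the sucrose response than the other libraries of its group, at 1.01 against 0.599 and 0.621, with ASN1 at 4.07 TPM and CAB1 at 12755 TPM against 25459 and 22687 TPM. Reads of CAB1 may be split with the other LHCB1 copies. A Col-0 sucrose library under a phyA-211 label is argued against by PHYA at 37.43 TPM, where the Col-0 sucrose libraries lay at 223 TPM or more. After median-ratio rescaling the position remained 0.981, against 0.594 and 0.608. That was nearly fixed by the measure, since 1 scale factor per library shifts signed rises and falls in opposite ways. It therefore does not test whether scaling by abundant transcripts altered the values of this library. No biological explanation was tested, and a sample that took up more sucrose or was collected differently stays open.

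Of the 15 clock genes, 7 were lower and 2 higher (LHY and RVE8) in phyA-211 under sorbitol, and 8 were lower and 3 higher (these and CCA1) under sucrose. All 9 clock genes called under sorbitol were called in the same direction under sucrose. Harvest of the mutant at another time of day would give this, and so would an effect of the mutation. The labels give no harvest times, so the explanations cannot be told apart, and loss of phytochrome A, a known input to the clock, stays open.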

How the results depend on the processing

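The fits without phyA-211 sucrose replicate 3 for the overlap, the ratios and the loci near PHYA were chosen after the data were seen, and so was the estimation method of the library weights. Limma's default estimate of those weights did not converge (0.0853 to 94.4), so its gene-by-gene estimate (0.192 to 4.89) was used. With it 1 library can dominate a group, as in Col-0 sucrose, where the weights were 0.506, 4.89 and 0.536. The weights come from the same libraries as the tests, so the counts they gave may be inflated. Of 263 calls of named genes, 197 kept their call in every setting that tested them, 66 were lost in some and 0 reversed. Of 48 list calls, 34 were kept in every setting but the estimated correlation and 14 were lost in some. Camera's direction reversed for 1 list, cytosolic ribosomal proteins for genotype under sucrose, with quantile normalization. Its median was then 0.082 and it was not called (camera adjusted p = 0.672). PHYA kept its call throughout.

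Rises and falls, in the order sucrose in Col-0, sucrose in phyA-211, genotype under sorbitol and genotype under sucrose, numbered 4777 and 4152, 7345 and 4057, 2729 and 2294, and 6158 and 2470 with library weights. These also gave 980 and 396 for the interaction and 13 lists for genotype under sorbitol. At least a doubling or halving left 579 and 540, 607 and 718, 76 and 136, and 179 and 292, as fewer genes can pass it. Only the groups compared gave 1621 and 1088, 93 and 178, and 266 and 388 in the last 3 comparisons. For sucrose in Col-0 it gave 2679 and 1987, not fewer than the main fit. Falls for genotype under sorbitol were 427 with median-ratio rescaling and 414 with quantile normalization. The interaction had 1 rise with no filter, with median-ratio rescaling, with quantile normalization, with the replicate block and with robust eBayes. An estimated correlation left 0, 0, 1, 2 and 0 lists in the 5 comparisons. At a threshold of 0.01 the overlap was 630 rises and 483 falls, as fewer genes pass. Ratios were 0.578 (phyA-211 over Col-0, without number 3), 0.617 and 0.941 (Col-0 over phyA-211, without numbers 1 and 2). For phyA-211 over Col-0 without number 2, that threshold left no ratio. Where no construction is named, the cause was not tested.

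Leaving out 1 library gave 1144 to 3149 rises and 1124 to 2356 falls for sucrose in Col-0, 1345 to 4152 and 982 to 2095 in phyA-211. For genotype it gave 49 to 319 and 103 to 465 under sorbitol, 254 to 930 and 315 to 693 under sucrose, and 0 to 2 rises for the interaction. Without any of the phyA-211 sucrose libraries, ath-MIR833a failed the TPM filter and was not tested, so its absence there says nothing of its call. Lists called were 11 to 12, 10 to 11, 7 to 10, 7 to 12 and 4 to 10. PHYA ranged from -3.39 to -3.22 under sorbitol and from -2.82 to -2.51 under sucrose. Without phyA-211 sucrose replicate 3, 3219 of the 5454 genes called for sucrose in phyA-211 were still called. The overlap was 1540 rises and 1122 falls, 7% of loci near PHYA were called, and the ratios were 0.832, 0.809, 0.671, 0.970 and 1.18. Where a lone pair remains, it is assumed to vary like the other groups.

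The data show no consistent pairing by replicate number: 6 of 18 same-number pairs deviated together at r over 0.1 (range -0.268 to 0.31) and 5 of 12 libraries lay closest to their own number. Number 3 of Col-0 sorbitol, phyA-211 sorbitol and Col-0 sucrose deviated together (r = 0.254, 0.31 and 0.252). That of phyA-211 sucrose did not join them (r = -0.105, -0.0324 and -0.107), and a shared batch is not excluded. With the replicate number as a block, rises and falls were 2181 and 1848, 2971 and 2005, 138 and 275, 637 and 649, and 1 and 0. All 48 list calls were kept, while 252 named gene calls were kept and 11 were lost. Depth is unknown, so no detection limit is given.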

Other observations

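The family tests, chosen after the data were seen, compared the share of called members of 175 protein families of at least 10 tested genes with that of all other genes (Fisher's exact test, 1400 tests, Benjamini-Hochberg adjustment), and 33 passed. Genes are not independent samples, so these p-values describe the lists. TCP-1/cpn60 chaperonins, which fold new proteins, rose with sucrose in 11 of 12 cases in Col-0 (adjusted p = 6.2e-07; median log2 change 0.69) and in 11 of 12 in phyA-211 (adjusted p = 5.7e-06; median 0.80). Histones, which package new DNA, rose in 17 of 28 cases in Col-0 (adjusted p = 6.86e-07; median 0.68) and in 12 of 28 in phyA-211 (adjusted p = 0.0385; median 0.42), and reads may be split between their near copies. DEA(D/H)-box RNA helicases rose in 13 of 18 and 12 of 18 cases (adjusted p = 1.71e-06 and 0.000366). Pseudouridine synthases, which modify RNA, rose in 10 of 17 and 11 of 17 (adjusted p = 0.000552 and 0.000971), and Endomembrane protein 70 genes in 6 of 10 and 9 of 10 (adjusted p = 0.0184 and 0.000134).

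RING/U-box proteins, many of them ubiquitin ligases, fell with sucrose in 51 of 184 cases in Col-0, 27.7% against 9.78% of other genes (adjusted p = 9.48e-09), and in 42 of 184 in phyA-211 (adjusted p = 0.000168). Iron-dependent 2-oxoglutarate oxygenases fell in 20 of 66 cases in phyA-211 (adjusted p = 0.000688). Between the genotypes, SNF7 proteins, subunits of membrane-sorting complexes, were higher in phyA-211 under sucrose in 5 of 10 cases (adjusted p = 0.00156). NAD(P)-binding Rossmann-fold proteins were lower in 8 of 102 cases under sorbitol, 7.84% against 1.35% of other genes (adjusted p = 0.00475). Under sucrose 12 of 102 were lower, 11.8% against 3.2% (adjusted p = 0.00595). The medians of this family were -0.03 and 0.05, so it did not move down as a whole. UDP-glycosyltransferases, which attach sugars to small molecules, were lower in 8 of 62 under sucrose, 12.9% against 3.22% of other genes (adjusted p = 0.0306). Their median log2 change was 0.03, so this family too did not move down as a whole. Whether families differ between genotypes in their sucrose response was not tested.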
